A study of Caenorhabditis elegans with 8 samples.

How the data were processed

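Whole-worm RNA of 8 samples was sequenced: 2 controls on the empty RNAi vector, 3 labelled as RNAi against vab-3 isoform A and 3 labelled as RNAi against isoform C. Per the labels' protocols, total RNA was isolated by phenol and chloroform extraction with QIAzol, and libraries were made with the TruSeq RNA kit v2, which does not mark the strand. Reads of overlapping or antisense genes can therefore not be told apart. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0 and featureCounts 1.5.0 were used and the genome build was WBcel235. The annotation release, the filters and the treatment of reads that match several genes are not given in the sources used here. A gene whose reads fit a near-identical copy, such as a major sperm protein gene, is therefore uncertain.

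The authors deposited a table of counts for 46739 genes, which holds whole numbers with column totals between 30289733 and 43364047. The deposited RPM table equals each count scaled to its column total, with a largest difference of 4.91e-11. The deposited RPKM values equal RPM divided by a length that is the same in all libraries for each gene, and they entered no test. Of these genes, 43720 have an identifier in the reference gene table of the same build, and 210 have an identifier but no symbol. These 210 hold 0.00685 to 0.0434% of the counts of a library and were kept. Gene symbols are those of the deposited table, and coordinates come from the reference annotation of build WBcel235. Samples were assigned to groups and replicate numbers by their titles and treatment labels.

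Genes were kept by edgeR's expression filter by group, which left 14772 genes with 99.9 to 100.0% of all counts. Library sizes were scaled by TMM factors between 0.957 and 1.02, and CPM values in the text use the scaled library sizes. Differences were tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood F test in a single model with 3 groups over all 8 libraries, because the control group holds only 2 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method in each of 3 comparisons, with a threshold of 0.05 and no fold threshold. Standard errors of log2 differences were taken as the size of the log2 difference divided by the square root of F. 42 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, again in the same model and adjusted over the lists of a comparison. No list passed camera with an estimated correlation in any of the 3 comparisons. The test fry was run beside it. It passed 3, 0 and 2 lists for A against control, C against control and A against C.

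The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took vab-3, the 8 genes with the largest and the 8 with the smallest log2 difference past the threshold in each comparison with control (5 and 5 between the RNAi groups) among genes with a symbol of the gene-class form and a mean of at least 5 CPM, and the 3 members with the smallest p of each list past the threshold. Where fewer than 10 genes passed, it took all of them and, as values only, the 10 genes of at least 5 CPM with the smallest p. Other genes named in the text were chosen after their values were seen.

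Replicates were compared before averaging. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.9 or more, so none was merged. Separate libraries of the same RNA could differ as much. Same-numbered libraries of the groups labelled isoform A and isoform C deviated from their group means together, with correlations across genes of 0.61, 0.43 and 0.22 for numbers 1, 2 and 3. Library 3 of isoform A correlated more with library 2 of isoform C than with library 3. Since all 3 pairs exceeded 0.1, the numbers were taken to pair these samples on the evidence of the data alone. No label says what a number stands for. The blocked value stands beside results of that comparison where it changes them. The block was thus taken up because of the same spread that it removes, so blocked counts and p-values may be too favourable. Deviations within a group cancel out, so the 3 correlations are not independent. The controls share only numbers 1 and 3 with each RNAi group, with correlations of 0.22 and 0.03 for isoform A and 0.32 and 0.20 for isoform C. Both values of isoform C exceeded 0.1. The deviations of 2 controls from their mean mirror each other, so these values cannot settle a pairing. The controls were not treated as paired, and blocked counts of genes are given beside those comparisons.

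The precision of a value is set by its counts: vab-3 had 64 to 170 counts per library, while kin-30 and chil-12 had 1 and 2 counts over all 3 isoform C libraries. Ratios of such genes are given with exact 95% counting intervals, which cover counting error only. The fits were tested on simulated counts for the 14772 genes, drawn with the means, spreads and sizes of the real libraries, with 200 genes changed per draw and 5 draws. For isoform A against control, 53.6% of 2-fold and 80.2% of 4-fold changes were recovered, with 6.40% false calls. For isoform C against control these shares were 47.0%, 77.6% and 8.24%, and for A against C they were 54.6%, 83.8% and 6.21%. Simulated genes varied independently of each other, and no simulated library differed from the rest of its group in many genes at once. The shares may therefore not hold for the real comparisons.

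Alternatives were other scaling factors (RLE, upper quartile, library size only), no filter, a filter of 10 counts in 6 libraries, DESeq2 1.42.0, limma-voom, limma on log2(RPM + 1), fits of only the groups compared, the replicate block, each library left out in turn, and other list tests. Added after the data were seen were a fit without isoform A libraries 2 and 3, a fit with the mean log2 CPM of moulting genes as a covariate, and a blocked fit of the 6 RNAi libraries alone. Every per-sample column of the 3 tables was matched to a sample.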

Results

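RNA from whole Caenorhabditis elegans hermaphrodites of the wild-type strain N2 was sequenced after RNA interference (RNAi), in which worms take up double-stranded RNA that matches a chosen gene. The treatments were aimed at isoform A or isoform C of vab-3, the worm counterpart of the vertebrate transcription factor gene Pax6. Synchronized animals were treated from young adulthood and collected on day 5 of adulthood. 2 control libraries (replicate numbers 1 and 3) came from worms on the empty vector, 3 libraries carry the label isoform A and 3 the label isoform C. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples only, which may be technical. Total counts per library ran from 30289733 to 43364047, and 18650 to 19675 genes had at least a single count. On the first principal component, which held 54.4% of the variance of the 8 libraries, isoform A libraries 2 and 3 lay at 64.6 and 54.7, while the other libraries lay between -40.0 and 1.06. Isoform A library 1 lay at -10.5 and correlated most closely with control library 1 (Pearson r = 0.993 across genes, which are not independent replicates).

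Counts of vab-3 were higher, not lower, in most libraries labelled as RNAi against it. The gene (WBGene00006870) lies on the forward strand of chromosome X from 10499890 to 10519580 in build WBcel235. Its longest annotated transcript, of isoform A, has 12 exons and spans nearly the whole gene, while the isoform C transcript has 6 exons and lies between 10516003 and 10519579. The level was 2.18 ± 0.0725 CPM (normalised read counts, mean ± SD, n = 2) in the controls, 4.78 ± 0.646 CPM (n = 3) in the libraries labelled isoform A and 3.65 ± 1.45 CPM (n = 3) in those labelled isoform C. All 3 isoform A libraries (4.43, 5.52 and 4.38 CPM) lay above both controls, as did isoform C libraries 1 and 3 (4.08 and 4.84 CPM), while isoform C library 2 lay at 2.04 CPM. The log2 difference from control was 1.13 ± 0.34 (SE) for isoform A (edgeR, adjusted p = 0.121) and 0.74 ± 0.33 for isoform C (edgeR, adjusted p = 0.700), and neither passed the threshold of 0.05. DESeq2 gave 1.12 ± 0.36 for isoform A with an adjusted p of 0.0332. The deposited counts are per gene, so the isoforms could not be told apart, and reads from the supplied double-stranded RNA would count toward the same gene. Because the targeted gene goes against the labels, the groups are called A-labelled and C-labelled libraries from here on, and a direction given for them is a direction between labelled libraries.

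**Figure D1:**
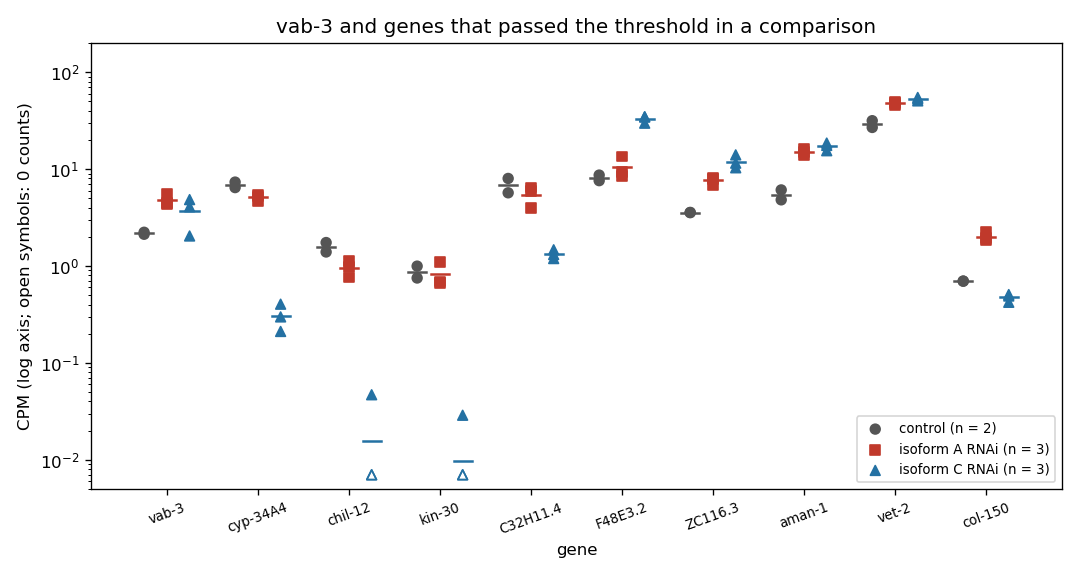
Level of vab-3 and of 9 genes past the threshold in a comparison, in CPM on a log axis. Each point is a library, short lines are group means, and open symbols stand for 0 counts and are drawn at a fixed height. The C-labelled libraries hold 0.304 CPM of cyp-34A4 on average, against 6.89 CPM in the controls and 5.09 CPM in the A-labelled libraries.

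The first comparison asked which transcripts differ between worms labelled isoform A RNAi and control worms. Genes that build the cuticle, the pharynx and the body wall muscle stood higher in the A-labelled libraries. Of 140 cuticle collagen genes tested, 133 were higher, with a median log2 difference of 2.32 (limma camera, adjusted p = 3.37e-15, adjusted p = 0.619 with an estimated correlation). All 26 pharynx genes were higher, with a median of 1.93 (camera, adjusted p = 8.04e-08, adjusted p = 0.619 with an estimated correlation). All 24 body wall muscle genes were higher as well, with a median of 1.07 (camera, adjusted p = 3.16e-09, adjusted p = 0.619 with an estimated correlation). Of 38 hedgehog-related and ground-like genes, which encode secreted proteins made largely by epidermal cells, 33 were higher, with a median of 1.40 (camera, adjusted p = 5.93e-05, adjusted p = 0.619 with an estimated correlation). No member of these lists passed over all genes tested. Adjusted over the list alone, 1 collagen, 15 pharynx genes, 20 muscle genes and 8 hedgehog-related genes passed as higher and 1 hedgehog-related gene as lower.

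Among the collagens, col-94 measured 41.2 ± 13.7 CPM in the A-labelled and 10.8 ± 0.881 CPM in the control libraries (log2 difference 1.93 ± 0.40, SE). The collagen gene col-118 measured 5.78 ± 1.69 against 2.13 ± 0.143 CPM, and col-150 measured 2.00 ± 0.217 against 0.697 ± 0.000375 CPM. In muscle, the paramyosin gene unc-15 measured 287 ± 99.0 against 111 ± 21.4 CPM. The tropomyosin gene lev-11 measured 222 ± 47.5 against 129 ± 8.22 CPM, and the actin gene act-4 501 ± 101 against 289.6 ± 10.5 CPM. Of the pharynx list, abu-12 measured 3.37 ± 2.05 against 0.434 ± 0.0440 CPM, abu-8 3.37 ± 1.53 against 0.824 ± 0.103 CPM, and phat-2 1.31 ± 0.886 against 0.160 ± 0.0389 CPM. The hedgehog-related genes grd-13, wrt-9 and wrt-10 had log2 differences of 2.16 ± 0.41, 2.82 ± 0.61 and 1.25 ± 0.32. All of these had an edgeR adjusted p of 0.121.

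These groups differed between the A-labelled libraries. The collagen list lay 0.35, 2.25 and 2.22 (mean log2) above the control mean in A-labelled libraries 1, 2 and 3. In the same order, the pharynx list lay 0.65, 2.21 and 1.79, the muscle list 0.54, 1.45 and 0.95, and the hedgehog-related list 0.39, 1.59 and 1.44. Genes expressed at larval moults, a list written after some of its members had been seen, moved with them, at 0.71, 2.29 and 1.90. With A-labelled libraries 2 and 3 both left out, an alternative chosen after the data were seen that leaves a single A-labelled library, the medians were 0.51 for collagens, 0.68 for the pharynx, 0.53 for muscle and 0.51 for hedgehog-related genes. As medians of log2 CPM differences from the control mean, A-labelled library 1 held 0.49, 0.69, 0.52 and 0.52. C-labelled library 2, the highest of its group, held 0.52, 0.69, 0.40 and 0.14. For collagens and pharynx, A-labelled library 1 was thus not set apart.

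**Figure D2:**
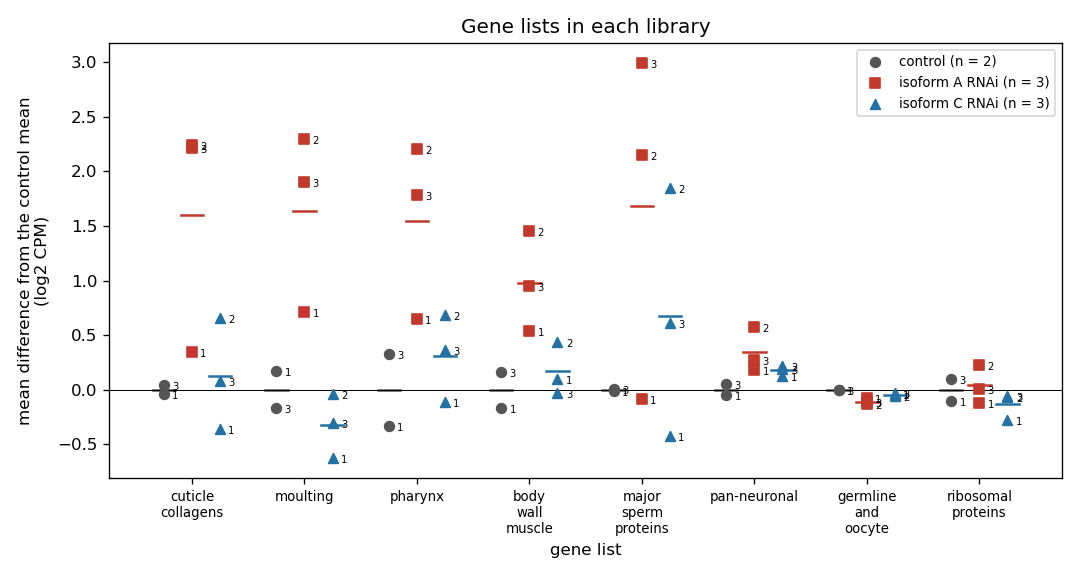
Mean difference of 8 gene lists from the control mean in each library, in log2 CPM, with the replicate number beside each point and short lines for group means. The collagen list lies at 2.25 and 2.22 in A-labelled libraries 2 and 3, at 0.35 in A-labelled library 1 and between -0.36 and 0.66 in the C-labelled libraries.

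Sperm, neuronal and early embryonic lists were also higher in the A-labelled libraries. All 31 major sperm protein genes tested were higher, with a median log2 difference of 2.37 (camera, adjusted p = 1.55e-04, adjusted p = 0.902 with an estimated correlation). They lay at -0.09, 2.15 and 3.00 in A-labelled libraries 1, 2 and 3, so the difference came from libraries 2 and 3, and the median was -0.21 with both left out. These genes are near-identical copies, so counts of single members such as msp-152 (2.72 ± 1.67 against 0.507 ± 0.0341 CPM), msp-3 (1.18 ± 1.07 against 0.164 ± 0.00353 CPM) and msp-76 (2.02 ± 1.63 against 0.388 ± 0.173 CPM) are uncertain. Of 12 early embryo genes, 11 were higher, with a median of 0.61 (camera, adjusted p = 0.00911, adjusted p = 0.451 with an estimated correlation). Its leading members, noah-1 (69.2 ± 26.9 against 23.02 ± 5.85 CPM), noah-2 (51.8 ± 22.3 against 16.37 ± 2.92 CPM) and let-653 (9.89 ± 0.653 against 5.59 ± 1.39 CPM), encode extracellular matrix proteins of epithelia that are also made at moults. Of 20 pan-neuronal genes, 17 were higher, with a median of 0.31 (camera, adjusted p = 0.00601, adjusted p = 0.619 with an estimated correlation). Among them were the synaptic release genes unc-13 (0.84 ± 0.19), unc-10 (0.90 ± 0.28) and snt-1 (0.63 ± 0.19). Of 14 neurotransmitter genes, 12 were higher, with a median of 0.58 (camera, adjusted p = 0.0263, adjusted p = 0.619 with an estimated correlation). The GABA synthesis gene unc-25 had a log2 difference of 1.04 ± 0.19 and the GABA transporter gene snf-11 of 1.58 ± 0.49, while tdc-1, which encodes tyrosine decarboxylase, had -0.25 ± 0.05. Adjusted over the list alone, 0 sperm protein genes, 3 early embryo genes, 1 pan-neuronal gene and 1 neurotransmitter gene passed as higher and 1 neurotransmitter gene as lower, against 0 over all genes tested.

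Of 62 lipase and beta-oxidation genes, 44 were higher, with a median of 0.15 (camera, adjusted p = 0.0263, adjusted p = 0.619 with an estimated correlation). The call was lost without control library 1 (camera, adjusted p = 0.116). The acyl-CoA dehydrogenase genes acdh-10 and acdh-6 had log2 differences of 0.28 ± 0.06 and 2.34 ± 0.64, and the acyl-CoA synthetase gene acs-9 had 1.76 ± 0.49. Germline and oocyte genes were lower, 21 of 30 of them, with a median of -0.09 (camera, adjusted p = 0.00187, adjusted p = 0.451 with an estimated correlation). Eggshell genes, 9 of 9, were lower with a median of -0.11 (camera, adjusted p = 0.0243, adjusted p = 0.619 with an estimated correlation), a call lost without control library 3 (camera, adjusted p = 0.0683). The Notch receptor gene glp-1 measured 355 ± 16.43 against 428 ± 0.407 CPM, the chitin synthase gene chs-1 775 ± 24.2 against 878 ± 21.1 CPM, and gna-2, which supplies its substrate, 198 ± 2.78 against 233 ± 2.67 CPM. The log2 differences of him-3, pie-1 and egg-3 lay at -0.25, -0.19 and -0.20. Adjusted over the list alone, 4 germline and 2 eggshell genes passed as lower and 0 lipase and beta-oxidation genes passed, against 0 over all genes tested.

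At the level of single genes, edgeR's quasi-likelihood test called 0 of 14772 genes between the A-labelled and control libraries. The smallest adjusted p was 0.0799, and 3840 genes had an unadjusted p below 0.05 (2024 higher, 1816 lower). DESeq2 called 1149 genes (772 higher, 377 lower), and both limma-voom and limma on RPM called 0. The genes with the smallest p, given as values, were aman-1, an alpha-mannosidase gene (15.1 ± 1.25 against 5.45 ± 0.903 CPM), and vet-2, an early embryonic transcript (47.9 ± 1.74 against 29.2 ± 3.30 CPM). They were followed by the prolyl 4-hydroxylase gene dpy-18, whose product modifies collagens (43.6 ± 2.69 against 27.5 ± 1.88 CPM), and the filamin gene fln-2 (61.5 ± 10.7 against 30.05 ± 2.82 CPM). The next were mca-2, alh-10, tag-196, hil-2 and mnr-1, with log2 differences of 0.75, 0.83, 0.45, 0.32 and 0.70, and the metaxin gene mtx-1, with -0.38. Without A-labelled library 1, 1303 genes passed (953 higher, 350 lower). A fit with the replicate number as a block called 546 genes (378 higher, 168 lower), though the controls were not taken as paired. In that fit 15 lists passed camera, against 11 without the block. No median of a list past the threshold in any of the 3 comparisons changed sign under the other scaling factors.

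The second comparison asked the same of the C-labelled libraries and the control libraries, and edgeR called 14 of 14772 genes, 9 higher and 5 lower. The cytochrome P450 gene cyp-34A4 (chromosome V, 3950023 to 3952097, forward strand, named dach-1 in the reference annotation) fell from 6.89 ± 0.634 CPM (n = 2) to 0.304 ± 0.0963 CPM (n = 3), a log2 difference of -4.50 ± 0.24 (edgeR, adjusted p = 4.03e-04). Adjacent genes on chromosome V, the chitinase-like gene chil-12 (15241559 to 15244003) and the kinase gene kin-30 (15244756 to 15247786), both on the forward strand, were nearly without counts. Over all libraries of a group, chil-12 had 107 counts in the controls and 2 in the C-labelled libraries, and kin-30 had 58 and 1. The control level was 88.1 times the C-labelled level for chil-12 (95% counting interval 23.8 to 737; edgeR, adjusted p = 0.0135) and 95.5 times for kin-30 (16.47 to 3836; edgeR, adjusted p = 0.0222). C32H11.4 (chromosome IV, 12921264 to 12923296) fell from 6.85 ± 1.63 to 1.32 ± 0.139 CPM (edgeR, adjusted p = 0.0147), and the cytochrome P450 gene cyp-25A2 from 18.7 ± 0.237 to 11.8 ± 0.0892 CPM (edgeR, adjusted p = 0.0449).

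The 9 genes that rose in the C-labelled libraries were led by F48E3.2 (chromosome X, 7490394 to 7493120), at 32.95 ± 2.78 CPM against 8.13 ± 0.757 CPM (log2 difference 2.02 ± 0.20, edgeR, adjusted p = 0.0135). ZC116.3, named cubn-1 after cubilin in the reference annotation (chromosome V, 12611329 to 12628749), rose from 3.56 ± 0.0119 to 11.94 ± 1.89 CPM. The alpha-mannosidase gene aman-1 (chromosome X, 4733095 to 4738592) rose from 5.45 ± 0.903 to 17.2 ± 1.57 CPM, and the early embryonic transcript vet-2 (chromosome I, 10846772 to 10850103) from 29.2 ± 3.30 to 52.8 ± 2.13 CPM. All 3 had an edgeR adjusted p of 0.0135. The chitinase gene cht-3 measured 552 ± 22.03 against 407 ± 13.5 CPM, the protease gene tag-196 50.1 ± 1.69 against 33.5 ± 0.504 CPM, and T22B2.1 13.8 ± 1.43 against 5.73 ± 0.169 CPM. F55B11.3 measured 47.1 ± 2.14 against 30.9 ± 0.832 CPM and T19D12.4 113 ± 8.54 against 69.95 ± 1.27 CPM. Of the 14 genes, the fixed rule for naming took aman-1, vet-2, tag-196, cht-3 and cyp-25A2, and the other 9 were named after their values had been seen.

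4 of the 42 lists passed between the C-labelled and control libraries. All 80 ribosomal protein genes tested lay lower, with a median log2 difference of -0.13 (camera, adjusted p = 4.60e-06, adjusted p = 0.986 with an estimated correlation). The list lay at -0.28, -0.07 and -0.06 in C-labelled libraries 1, 2 and 3 against -0.10 and 0.10 in the controls, and without control library 3 its median was -0.02 (camera, adjusted p = 0.488). F54D7.6, named rpl-41.1 in the reference, measured 61.7 ± 4.21 against 75.9 ± 0.106 CPM, and rpl-38 and rpl-29 had log2 differences of -0.21 ± 0.08 and -0.26 ± 0.11. Of 27 DNA replication and cell cycle genes, 19 were higher, with a median of 0.08 (camera, adjusted p = 0.00126, adjusted p = 0.986 with an estimated correlation; camera, adjusted p = 0.0609 without control library 3). Among them were rnr-1 (0.21 ± 0.05), top-2 (0.23 ± 0.06) and mcm-4 (0.15 ± 0.04). Of 31 sperm protein genes, 30 were higher, with a median of 1.19 (camera, adjusted p = 0.0378, adjusted p = 0.986 with an estimated correlation). They lay at -0.42, 1.85 and 0.61 in C-labelled libraries 1, 2 and 3, and without library 2 the median was 0.32 (camera, adjusted p = 0.867). The call was also lost without control library 1, control library 3, A-labelled library 2 or C-labelled library 3 (camera, adjusted p = 0.152, 0.0584, 0.127 and 0.0712). Of its leading members, msp-65 measured 0.621 ± 0.436 against 0.220 ± 0.0299 CPM, and msp-64 and msp-33 had log2 differences of 1.88 and 1.78. Of 20 pan-neuronal genes, 17 were higher, with a median of 0.15 (camera, adjusted p = 0.0378, adjusted p = 0.986 with an estimated correlation). They were led by unc-18 (0.40 ± 0.13), unc-13 (0.36 ± 0.19) and ida-1 (0.35 ± 0.21). That call was lost without control library 1, C-labelled library 2 or C-labelled library 3 (camera, adjusted p = 0.276, 0.120 and 0.0712). No member of these 4 lists passed over all genes tested or adjusted over the list alone. The collagen, muscle and pharynx lists did not pass, with medians of 0.13, 0.14 and 0.28 (camera, adjusted p = 0.845, 0.212 and 0.119).

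The count of 14 genes depended on each library of this comparison, and an unadjusted p below 0.05 was held by 1084 genes. It was 2 without control library 1, 1 without control library 3, and 3, 3 and 6 without C-labelled libraries 1, 2 and 3. Only cyp-34A4 passed in each of these fits and in those without an A-labelled library (edgeR, adjusted p up to 0.00618). DESeq2 called 155 genes (123 higher, 32 lower), 12 of the 14 among them. A fit with the replicate number as a block called 102 genes (54 higher, 48 lower), all 14 among them. In that fit 3 lists passed camera, against 4 without the block.

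The third comparison set the A-labelled directly against the C-labelled libraries, and edgeR called 6 of 14772 genes, 5 higher in the A-labelled libraries and 1 lower. cyp-34A4 measured 5.09 ± 0.420 CPM in the A-labelled and 0.304 ± 0.0963 CPM in the C-labelled libraries (n = 3 each; log2 difference 4.07 ± 0.23, edgeR, adjusted p = 6.48e-04). The A-labelled libraries held 99 counts of chil-12 and 82 of kin-30 in total, against 2 and 1 in the C-labelled libraries (edgeR, adjusted p = 0.0337 for both). C32H11.4 measured 5.45 ± 1.33 against 1.32 ± 0.139 CPM (edgeR, adjusted p = 0.0366), the collagen gene col-150 (chromosome V, 10293563 to 10294649, reverse strand) 2.00 ± 0.217 against 0.473 ± 0.0449 CPM and F48E3.2 10.4 ± 2.67 against 32.95 ± 2.78 CPM (edgeR, adjusted p = 0.0337 for both). With the replicate number as a block, 1702 genes passed (1133 higher, 569 lower), all 6 among them. The block was taken up on the evidence of these same libraries, so this count may be too favourable. In this comparison 2840 genes had an unadjusted p below 0.05, and DESeq2 called 663 (558 higher, 105 lower).

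17 of the 42 lists passed between the A-labelled and C-labelled libraries, 12 higher and 5 lower in the A-labelled ones. Of 140 collagen genes, 137 were higher, with a median of 1.72 (camera, adjusted p = 4.32e-18, adjusted p = 0.533 with an estimated correlation). They include col-54 (4.06 ± 0.66; edgeR, adjusted p = 0.137, and 0.00542 with the block) and col-131 (3.39 ± 0.62; edgeR, adjusted p = 0.137, and 0.00557 with the block). All 24 muscle genes were higher, with a median of 0.87 (camera, adjusted p = 2.81e-09, adjusted p = 0.560 with an estimated correlation). They include the actin gene act-4 (0.70 ± 0.17; edgeR, adjusted p = 0.140, and 0.0151 with the block) and the troponin genes tni-1 and mup-2 (1.45 ± 0.36 and 0.95 ± 0.23). All 26 pharynx genes were higher, with a median of 1.32 (camera, adjusted p = 1.04e-06, adjusted p = 0.630 with an estimated correlation), including phat-4 (2.67 ± 0.59; edgeR, adjusted p = 0.137, and 0.0111 with the block). Of 38 hedgehog-related genes, 31 were higher, with a median of 1.40 (camera, adjusted p = 1.59e-06, adjusted p = 0.533 with an estimated correlation), including grd-13 (2.25 ± 0.35; edgeR, adjusted p = 0.137, and 0.00350 with the block). Over all genes tested, 1 collagen gene, col-150, passed and no gene of the other 3 lists did, against 57 collagens, 20 muscle genes, 10 pharynx genes and 25 hedgehog-related genes higher, and 1 of the last lower, adjusted over the list alone. With the block, 44 collagens, 11 muscle genes, 13 pharynx genes and 16 hedgehog-related genes passed as higher over all genes tested.

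Lists of the epidermis, glia and nerve terminals followed with smaller medians. Of 18 epidermal antimicrobial peptide genes, 17 were higher in the A-labelled libraries, with a median of 0.32 (camera, adjusted p = 0.0332, adjusted p = 0.648 with an estimated correlation). They include nlp-33 (17.6 ± 5.55 against 8.41 ± 1.09 CPM; edgeR, adjusted p = 0.137, and 0.0214 with the block). This call was lost without A-labelled library 1 or C-labelled libraries 2 or 3 (camera, adjusted p = 0.129, 0.0509 and 0.159). Of 8 glial genes, 7 were higher, with a median of 0.51 (camera, adjusted p = 0.0183, adjusted p = 0.525 with an estimated correlation). They include the glutamate transporter gene glt-1 (58.1 ± 9.23 against 42.2 ± 3.62 CPM; edgeR, adjusted p = 0.137, and 0.00624 with the block). Of 14 neurotransmitter genes, 11 were higher, with a median of 0.53 (camera, adjusted p = 0.0193, adjusted p = 0.533 with an estimated correlation), including unc-25 (0.54 ± 0.16; edgeR, adjusted p = 0.170, and 0.0471 with the block). Of 12 early embryo genes, 9 were higher, with a median of 0.65 (camera, adjusted p = 0.0152, adjusted p = 0.395 with an estimated correlation; camera, adjusted p = 0.0582 without A-labelled library 1), led by noah-1, noah-2 and let-653 (1.82, 1.91 and 0.77). All 31 sperm protein genes were higher, with a median of 1.22 (camera, adjusted p = 0.0152, adjusted p = 0.909 with an estimated correlation). That call was lost without A-labelled libraries 2 or 3 or C-labelled library 1 (camera, adjusted p = 0.0751, 0.432 and 0.297), and with A-labelled libraries 2 and 3 both left out the median was -1.42. Adjusted over the list alone, 3 antimicrobial peptide genes, 4 glial genes and 4 early embryo genes passed as higher and 1 glial gene as lower, against none over all genes tested, and no neurotransmitter or sperm protein gene passed either way. With the block, 6 antimicrobial peptide genes, 3 glial, 4 early embryo and 2 neurotransmitter genes and 1 sperm protein gene passed as higher over all genes tested, and 1 glial gene as lower.

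Metabolic lists were higher by small amounts. Of 80 ribosomal protein genes, 79 were higher in the A-labelled libraries, with a median of 0.17 (camera, adjusted p = 1.59e-06, adjusted p = 0.909 with an estimated correlation). With only library 1 of the A-labelled group the median was 0.01. Of 49 nuclear-encoded oxidative phosphorylation genes, 45 were higher, with a median of 0.09 (camera, adjusted p = 0.00202, adjusted p = 0.909 with an estimated correlation; camera, adjusted p = 0.0543 without A-labelled library 2). Of 62 lipase and beta-oxidation genes, 48 were higher, with a median of 0.14 (camera, adjusted p = 0.0152, adjusted p = 0.533 with an estimated correlation). Its leading members were the peroxisomal acyl-CoA oxidase genes acox-2 and acox-3, named acox-1.2 and acox-1.3 in the reference, which act in ascaroside pheromone synthesis. acox-2 measured 15.6 ± 4.52 against 4.59 ± 0.751 CPM (edgeR, adjusted p = 0.137, and 0.00112 with the block) and acox-3 4.20 ± 1.06 against 1.94 ± 0.221 CPM (edgeR, adjusted p = 0.137, and 0.00973 with the block). Adjusted over the list alone, 8 lipase and beta-oxidation genes passed as higher and 2 as lower, and no ribosomal or oxidative phosphorylation gene passed, against none of the 3 lists over all genes tested. With the block, 29 ribosomal, 3 oxidative phosphorylation and 11 lipase and beta-oxidation genes passed as higher over all genes tested, and 3 of the last list as lower.

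Germline-related and signalling lists were lower in the A-labelled than in the C-labelled libraries. Of 31 small RNA pathway genes, 26 were lower, with a median of -0.11 (camera, adjusted p = 3.47e-04, adjusted p = 0.247 with an estimated correlation). They include the Argonaute gene hrde-1 (-0.18 ± 0.05; edgeR, adjusted p = 0.162, and 0.0308 with the block) and rde-4, which encodes a double-stranded RNA binding protein of the RNAi pathway (-0.15 ± 0.04; edgeR, adjusted p = 0.144, and 0.0347 with the block). Of 27 DNA replication and cell cycle genes, 25 were lower, with a median of -0.06 (camera, adjusted p = 3.47e-04, adjusted p = 0.525 with an estimated correlation). Among them was rnr-2 (-0.17 ± 0.04; edgeR, adjusted p = 0.137, and 0.0328 with the block). Of 30 germline and oocyte genes, 22 were lower, with a median of -0.05 (camera, adjusted p = 0.0152, adjusted p = 0.395 with an estimated correlation). Among them was pie-1 (-0.23 ± 0.05; edgeR, adjusted p = 0.137, and 0.0139 with the block). All 9 eggshell genes were lower, with a median of -0.07 (camera, adjusted p = 0.0332, adjusted p = 0.525 with an estimated correlation). Of 17 insulin and TOR signalling genes, 13 were lower, with a median of -0.08 (camera, adjusted p = 0.0255, adjusted p = 0.533 with an estimated correlation). Both of these calls were lost without A-labelled library 1 (camera, adjusted p = 0.0707 and 0.0752) or library 2 (camera, adjusted p = 0.0751 for both). Adjusted over the list alone, 1 germline gene passed as lower, and no gene of the other lower lists, against none over all genes tested. With the block, 7 germline, 5 small RNA pathway and 4 DNA replication genes and 1 insulin and TOR signalling gene passed as lower over all genes tested, 1 small RNA pathway gene as higher, and 0 eggshell genes.

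The genes with the smallest p after these 6, given as values, included the lipocalin-related genes lpr-4 (11.396 ± 7.06 against 0.920 ± 0.205 CPM) and lpr-3 (25.3 ± 12.9 against 4.32 ± 0.350 CPM) and dao-2 (25.07 ± 9.20 against 5.97 ± 0.692 CPM). The ferroportin-related gene fpn-1.1 measured 25.98 ± 1.06 against 36.1 ± 1.95 CPM. All 4 had an edgeR adjusted p of 0.137, and with the block lpr-4, dao-2 and fpn-1.1 passed (edgeR, adjusted p = 0.0213, 0.0403 and 0.00653) and lpr-3 did not (edgeR, adjusted p = 0.0640). With the block 18 lists passed the camera test with the preset correlation and 0 with an estimated correlation, the added list being transcription factor genes related to vab-3 and genes of its partners, such as eya-1 and ceh-32. All 7 of them tested were higher, with a median of 0.38 (camera, adjusted p = 0.144 without and 0.0276 with the block, adjusted p = 0.474 with the block and an estimated correlation). By fry, which asks whether a list's genes move on balance in a single direction, 2 lists passed without and 12 with the block. Without any single library among control libraries 1 and 3, A-labelled libraries 2 and 3 and C-labelled libraries 1, 2 and 3, the count of 6 genes fell to 1, cyp-34A4, and without A-labelled library 1 it was 748.

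Both comparisons with control use the same 2 control libraries, which could not be split into pairs. Since edgeR called 0 genes in the A-labelled libraries, its calls could not be compared, and DESeq2 called 73 genes in both. All 14 genes called in the C-labelled libraries had the same sign in the A-labelled ones, and 9 of them had an unadjusted p below 0.05 there. In 40 simulations all 8 libraries were redrawn without group differences, with the 2 controls again shared by both comparisons. Of the 14 genes with the smallest p there, a median of 14 had the same sign (lowest 12). A median of 10 had an unadjusted p below 0.05 in the A-labelled comparison (7 to 14), so in the simulations shared controls alone gave as much. Genes were drawn independently and with a single spread for all groups, unlike the real libraries, so the real share from the controls may differ. Among the called genes, aman-1 and vet-2 were the genes with the smallest p in the A-labelled comparison too. Across all genes, which are not independent replicates, the log2 differences of both comparisons correlated with r = 0.476, against a median of 0.609 (0.591 to 0.634) in these simulations. Their covariance was 0.122 against a simulated 0.0796 (0.0751 to 0.0872), a difference of 0.0420. The same sign was held by 71.6% of genes, against 70.5% (69.7 to 71.4%) in the simulations. The correlation thus lay below all 40 simulations, while the covariance and the share of equal signs lay above them. Part of any excess over independent lists may come from the shared controls, which the simulations also held.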

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

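The tests of somatic RNA, control material in A-labelled library 1, depth, the cytochrome P450 cluster, a deletion, supplied double-stranded RNA and moulting content for vab-3 were chosen after the results were seen, as was the choice to leave noah-2 and lpr-3 out of the moulting genes.

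A direct test between the groups singled out 6 genes whose difference from control was not alike in the A-labelled and C-labelled libraries. The log2 difference, A-labelled minus C-labelled, was 4.07 for cyp-34A4 (edgeR, adjusted p = 6.48e-04), 6.02 for kin-30, 5.49 for chil-12, 2.07 for col-150 and -1.66 for F48E3.2 (edgeR, adjusted p = 0.0337 for these 4), and 2.04 for C32H11.4 (edgeR, adjusted p = 0.0366). The values of kin-30 and chil-12 are fitted to 1 and 2 counts in the C-labelled libraries and set no bound. The 6 RNAi libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 6 genes and the highest other 0, and 1 of the 10 splits gave as many. For lists the real split gave 17 and the highest other 17, and 4 of the 10 splits gave as many. Of the 4 splits that part all 3 replicate numbers, the real one gave 17 lists and the highest other 10.

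In the C-labelled libraries cyp-34A4, chil-12 and kin-30 were low in every library, and a lower depth is argued against, since the control level would give 1031 counts of the 3 genes together where 36 were seen. A change of the whole cytochrome P450 cluster is also argued against: the other cyp-34A, cyp-35A and cyp-35B genes tested had a median log2 difference of -0.068 (quartiles -0.40 to 0.27) against -4.50 for cyp-34A4. The adjacent chil-12 and kin-30, 752 bp apart, had 3 counts together. The nearest tested genes, plc-2 at 43934 bp before and M01B2.10 at 13103 bp after the pair, had log2 differences of -0.08 and 0.13. They bound the loss only loosely, and M01B2.10 measured only 2.90 CPM in the controls. A deleted locus in the worms of these libraries and a loss of transcription cannot be told apart, because the counts hold no genomic reads. Whether the loss comes from the RNAi treatment or from the line of worms used for it stays open, as the label and the line could differ together.

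Cuticle, muscle and pharynx genes were higher in the A-labelled libraries, most in libraries 2 and 3, and in those 2 a larger share of all somatic RNA is argued against as the whole cause: the 3 lists exceeded pan-neuronal and intestine genes by at least 0.535 more than in any control or C-labelled library. A-labelled library 1 made wholly of control material is argued against, though only by 1 library set against 1 control at a time. With control 1 and then control 3 held out, 23 genes were chosen for parting C-labelled libraries from the other control. Of these, 20 and 16 lay toward the C-labelled level in library 1 relative to the held-out control, by the sign of the difference alone. Some of these differences were small, such as that of kin-30 (0.69 against 0.75 CPM with control 1 held out). Among the genes counted in both were aman-1 (15.02 CPM against 6.09 and 4.81) and vet-2 (48.1 CPM against 31.6 and 26.9). Both counts use the same library 1, so they are not independent. For library 1 a larger share of somatic RNA stays open, as the collagens exceeded pan-neuronal and intestine genes by 0.392 there and by up to 0.348 in the C-labelled libraries, a margin of only 0.0444. Moulting or larval animals among the collected worms are a candidate explanation. In the A-labelled libraries 11 moulting genes not named elsewhere had a median of 2.18 (0.012 in the C-labelled libraries). The central 95% of random lists of like expression ended at 0.47. Those lists were drawn gene by gene, so this bound does not allow for genes that move together in a library. An effect of the treatment on adults stays open and untested. Whole-worm counts cannot tell adults with more of the cuticle, muscle and pharynx transcripts from larval animals among them.

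Counts of vab-3 were higher in most libraries labelled as RNAi against it, by 1.13 (log2) in the A-labelled libraries. Reads from the supplied double-stranded RNA and transcripts of the worm cannot be told apart, since the counts are not given per exon. For moulting or larval content the A-labelled libraries cannot decide, since their moulting scores (0.219 or more) all exceeded those of the controls (-0.321 and -0.661). C-labelled libraries 1 and 3 had lower scores than both controls, -1.12 and -0.796. Their vab-3 levels of 4.08 and 4.84 CPM still exceeded the higher control at 2.23 CPM, so a higher score did not go with the higher level there. C-labelled library 2, with a score of -0.532, had 2.04 CPM and did not exceed that control. The test asked for every RNAi library with a score at or below the higher control to exceed it, so it cannot decide.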

How the results depend on the processing

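The fit without A-labelled libraries 2 and 3, the moulting covariate and the blocked fit of the 6 RNAi libraries were chosen after the data were seen. Of 2749 values of named genes under alternatives, 2335 kept their direction and their side of the threshold, 133 no longer passed, 255 newly passed and 26 reversed. The cause was not tested for any change below unless given. With RLE, upper-quartile or library-size scaling, edgeR called 0 genes each for A-labelled against control, 13, 12 and 12 for C-labelled against control and 6, 6 and 7 between the RNAi groups, but with upper-quartile factors 2 lists passed for C-labelled against control in place of 4. Without a filter 8 and 12 genes passed for A-labelled against control and against C-labelled, and 4 were shared with the C-labelled calls. DESeq2 called 1149, 155 and 663 genes in the 3 comparisons, 73 of them in both comparisons with control, and gave 1.12 for vab-3 in the A-labelled libraries (DESeq2, adjusted p = 0.0332). limma on RPM called 3 genes between the RNAi groups. Fits of only the groups compared called 23 for C-labelled against control and 1 between the RNAi groups, with fewer samples to estimate spread. The replicate block gave 546, 102 and 1702 genes and 38 shared, and on the 6 RNAi libraries alone 1616. At an adjusted p below 0.1 edgeR shared 1 gene. Leaving out each library in turn gave 0 to 1303, 1 to 15 and 1 to 748 genes, 0 to 8 shared, and 11 to 15, 3 to 7 and 13 to 20 lists. Where a fit left a single control or, in the fit without A-labelled libraries 2 and 3, a single A-labelled library, that library was assumed to vary like the other groups. An estimated correlation passed 0, 0 and 0 lists and fry 3, 0 and 2. Without A-labelled libraries 2 and 3, 25 genes passed for C-labelled against control, and between the RNAi groups msp-152, msp-45 and msp-3 reversed to -0.25, -1.68 and -0.76. The moulting covariate left 0 genes between the RNAi groups and 8 lists for C-labelled against control. It is the mean of genes partly chosen for moving with the A-labelled libraries, and it lay from 0.219 to 1.802 in these and from -1.12 to -0.532 in the C-labelled ones. Since it parts the groups completely, it takes up some of their difference, and what it changes says nothing about moulting. With it the difference of cyp-34A4 between the RNAi groups went from 4.07 ± 0.23 (SE) to 3.91 ± 0.40, of kin-30 from 6.02 ± 0.67 to 5.49 ± 1.06, of chil-12 from 5.49 ± 0.61 to 5.85 ± 0.92 and of col-150 from 2.07 ± 0.21 to 1.97 ± 0.42, so these calls ended mostly by the wider spread. Those of C32H11.4 (2.04 ± 0.23 to 1.35 ± 0.42) and F48E3.2 (-1.66 ± 0.17 to -1.09 ± 0.28) also shrank. With it, values against control in the A-labelled libraries reversed to -0.43 for msp-152, -0.48 for msp-3, -0.77 for msp-76 and -0.0082 for acdh-6. Between the RNAi groups they reversed to 0.028 for spn-4, 0.047 for chs-1, -1.80 for msp-152, -2.97 for msp-45, -2.23 for msp-3, -0.66 for snf-11, -0.30 for daf-6 and for ptr-10, -0.37 for tni-1, -0.21 for mup-2, -0.42 for abu-12, -0.35 for phat-4, -0.66 for phat-2, -0.059 for wrt-9, -0.52 for nlp-24, -0.016 for rps-20 and for asg-2, -0.16 for rps-17 and -0.047 for gas-1. Depth limits the ratios of kin-30 and chil-12, with 1 and 2 counts in the C-labelled libraries.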

Other observations

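No test in this part was chosen after its result was seen, but the genes named here were. Early embryonic transcripts of the vet, pes and sdz classes were mostly higher in both RNAi groups. The genes vet-2, a gene past the threshold in the C-labelled libraries, and pes-10 and vet-1, which did not pass, led to a list of vet, pes and sdz genes not looked at before. Of its 37 genes, 35 were higher in the A-labelled libraries, with a median log2 difference of 0.38, where the central 95% of random lists of like expression ended at 0.32. In the C-labelled libraries 32 were higher, with a median of 0.32, where the random lists ended at 0.10. The random lists were drawn gene by gene. Their bounds do not allow for genes that move together in a library and may be too narrow. The list of early embryo genes fixed beforehand, led by matrix genes, had 5 of 12 genes higher in the C-labelled libraries and a median of -0.21. More early embryos inside the RNAi-treated animals are a candidate explanation that the values of the vet, pes and sdz genes fit. The counts hold no number of embryos, and both comparisons rest on the same 2 control libraries, so a low level in these controls stays open.

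Heat shock genes stood higher in the libraries numbered 1 of all 3 groups, which was not tested. The mean of the 18 genes of the list lay 0.59, 0.58 and 0.63 (log2) from the control mean in the libraries numbered 1 and between -0.59 and -0.19 in the other 5. hsp-70 measured 27.99, 26.8 and 21.7 CPM in the libraries numbered 1 of the control, A-labelled and C-labelled groups, and between 2.52 and 5.15 CPM in the others. hsp-16.2 measured 20.96, 16.54 and 19.02 CPM in the libraries numbered 1 and between 2.11 and 4.50 CPM in the others. The labels give no batch or date. hsp-16.2 belongs to a family of related genes, so the assignment of its reads may be uncertain.

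The cuticle collagen gene bli-1 and the moulting gene mlt-10 show the spread of the A-labelled libraries. bli-1 measured 0.316, 6.56 and 28.6 CPM in A-labelled libraries 1, 2 and 3 against 0.429 and 0.531 CPM in the controls, and mlt-10 measured 10.5, 26.1 and 30.4 CPM against 8.16 and 8.43 CPM.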
